A study of Drosophila melanogaster with 3 samples.

How the data were processed

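Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done, per the labels, with an anti-GFP antibody on whole embryos of mixed sex aged 0 to 24 h. The embryos came from a transgenic Drosophila melanogaster line that expresses slou with a C-terminal eGFP. Per the labels' protocols the chromatin was sheared by sonication. The 3 samples are biological replicates of 1 group, named replicates 1, 2 and 3 by the labels' replicate numbers. No control library is among the samples, so no groups were compared. All comparisons are between replicates or between genomic features.

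Per the deposited README files, peaks were called in each replicate and on the replicates pooled, in each case with a control alignment, and an optimal list was derived for the series. Each replicate list holds 30000 peaks and was made as input for a rank-based reproducibility procedure, so it holds background as well as signal. Lists were deposited for the builds dm6 (BDGP Release 6) and dm3. The aligner, the peak caller and their versions are not given in the sources used here. The deposited score of each peak is the authors' own value from their peak caller, on a scale that no source used here states. It served only to rank, filter or describe peaks within a list. The deposited −log10 q of each peak is also the authors' value and served only to describe the lists. The column for −log10 p was empty in all lists. In dm6, every optimal peak was an identical row of the pooled list, and the 2743 optimal peaks were the 2743 highest-scoring of its 30000 peaks. No read counts are in the files used, so sequencing depth is unknown. The intervals given for shares are 95% Wilson intervals over peaks and cover counting error only. Neighbouring peaks are not independent. Peaks, sequence windows or transcription start sites, not libraries, are the units of all Fisher and McNemar tests.

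The dm6 lists were analysed with Ensembl release 115 gene models (BDGP 6.54) and the RefSeq Release 6 genome, whose arm lengths exceeded every peak coordinate. The dm3 lists were used only within dm3, without annotation, and no coordinate was converted. Coordinates are dm6 and 1-based. The summit is the deposited summit offset, which was the middle of the interval for 29690 of 30000 pooled-list peaks and 2435 of 2743 optimal peaks.

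Replicate support was the share of optimal peaks overlapped by at least 1 bp by any of the 2743 highest-scoring peaks of a replicate. Chance came from 1000 random placements of the optimal peaks on the same arms with the same widths. Agreement of a replicate pair was the share of the 2743 highest-scoring peaks of the lower-numbered replicate that overlapped those of the other. Spearman's rho of the score was taken over overlapping pairs, across peaks, without a p. Background peaks were the 26843 pooled-list peaks that overlap no optimal peak. Chromosome arms and position classes were compared between optimal and background peaks with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 6 arms and over 7 classes. A summit within 500 bp of a protein-coding transcription start site (TSS) was placed in the TSS class, and the others in order of priority in 5′ UTR, 3′ UTR, CDS, noncoding exon, intron or intergenic sequence.

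A gene was counted as bound when an optimal summit lay in its body or 1 kb upstream. For 17 gene lists, the share of bound genes was set against 10000 random lists drawn from genes with a pooled-list peak in the same window, matched on window length in 10 classes, with a two-sided permutation p and adjustment over the lists. All 541 list symbols were matched to the annotation, 3 of them under a newer symbol. The homeodomain core TAATTA, and TAATTG on either strand, were searched within 50 bp of each summit. Summits were compared with windows centred 500 bp to each side by an exact McNemar test and with background peaks by Fisher's exact test, both two-sided. All 2080 strand-merged 6-mers were compared between summits and the side windows by a two-sided Fisher's exact test with adjustment. It ignores the pairing of a summit with its own side windows.

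The genes and sequences named were chosen by a rule. It takes slou, the protein-coding gene with the nearest TSS for the 20 highest-scoring optimal peaks, and the 10 genes with most optimal summits. It also takes up to 4 members of each list by their highest peak, and the 6 more frequent and 2 less frequent 6-mers with the smallest p. Names outside it are said to be chosen after the values were seen. The rule, the lists, the tests and most alternatives were fixed before the data were examined.

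The alternatives were stricter overlap, matching of summits within 100 bp, list lengths of 1371 and 5486, the dm3 lists, the 1371 optimal peaks with the higher score, the peaks matched in all 3 replicates, and leaving out each replicate in turn, which for tests over peaks kept the optimal peaks matched in both others. Others were another background, TSS distance, gene window, length matching, summit window or side window. Comparisons within classes of equal A/T share (Mantel-Haenszel), the comparisons of arms with protein-coding TSSs, for all optimal peaks and for those in the TSS class, with adjustment over 7 arms including Y, and the pair left without each replicate were chosen after seeing the data. The Mantel-Haenszel comparisons with side windows also ignore the pairing of a summit with its own side windows. The statistics were tested on simulated data. Peaks shifted by up to 50 bp were all found again. With TSS peaks drawn at a weight of 5, the median odds ratio of TSS position was 5.23. A planted 6-mer had the smallest p of 2080. With A/T-richer windows and no planted core, the odds ratio of TAATTA at equal A/T share was 1.02 at the median, and with the core planted in 5% of windows 100% of draws had a p under 0.05. Of 200 simulated lists of 19 genes with 3 times the odds of being bound, 54.5% had a p under 0.05 before adjustment, against 26% for lists of 10 genes and 100% for lists of 85 genes. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.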

Results

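Binding of slouch (slou), an NK-type homeodomain protein that specifies muscle and neuron identity, was profiled in whole Drosophila melanogaster embryos aged 0 to 24 h. An anti-GFP antibody was used on embryos carrying slou fused to eGFP, in 3 biological replicates that form 1 group. The dm6 optimal list held 2743 peaks, 9.14% of the pooled list, and 88.6% of them were 390 bp wide. The authors' own score ranged from 92.0 to 1515 with a median of 136, and 58.8% of the peaks lay at the highest −log10 q of the list, 3.03. The depth of each library is unknown.

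The highest-scoring peak lay at 2L:480912-481263, in an intron of ush, which encodes a cofactor of GATA factors, and 1396 bp from the nearest TSS, that of the zinc-finger gene cbt. It had a score of 1515. The next peaks lay 86 bp from the TSS of CG14100 (3L:19590441-19590810, score 1515) and 146 bp from that of mRpL41, a mitochondrial ribosomal protein gene (2R:15217586-15217925, score 1330). The others of the 20 highest were nearest to CG11050, HmgZ, px, Ugalt, ph-p, Art3, Chro, CG5611, Trl, SLC5A11, CG4004, CG32772, Atat, Lk6, CenG1A, CG13390 and CG8320. Among these, Trl encodes the GAGA factor, Chro a chromodomain protein, and ph-p a Polycomb group protein with a tandem paralog. Of the 20 summits, 13 were in the TSS class, 6 in introns and 1 in a noncoding exon. All 20 were among the top 2743 peaks of each replicate, with no rank below 33 in any of them.

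The genes with most optimal summits were led by ush and CG1677. Both ush (2L:476220-540560) and CG1677 held 10, the forkhead gene CHES-1-like 9, and kirre, which encodes an adhesion protein of myoblast fusion, and shn, a zinc-finger gene of Dpp signalling, held 8 each. The genes sbb, Tlk, dnc, Hr4 and CG32264 held 7 each. The window of kirre spans 395149 bp and held 105 pooled-list summits, against 28048 bp and 17 for CHES-1-like. In all, 2748 of the 8832 protein-coding genes with a pooled-list peak were bound (31.1%).

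The slou gene itself (FBgn0002941, 3R:21548661-21557182, minus strand) had no optimal summit in its body or 1 kb upstream. It held 4 pooled-list summits, the best of them at rank 15376. The optimal summit nearest to the slou TSS lay in an intron of InR, the insulin receptor gene, at 3R:21590861, 33679 bp away, at rank 216. The one nearest to the gene body lay on its other side at 3R:21520380, 28281 bp from the body and 36802 bp from the TSS, at rank 44. It was intergenic, and upstream of the TSS of sp3 at -548 bp, a gene named after its values were seen. Within 20 kb of the middle of slou there were 25 pooled-list summits. The best of these, at 3R:21563331-21563720, was 6344 bp from the slou TSS and ranked 2764, 21 places below the optimal list. It ranked 1269, 3375 and 4847 in replicates 1, 2 and 3.

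**Figure D1:**
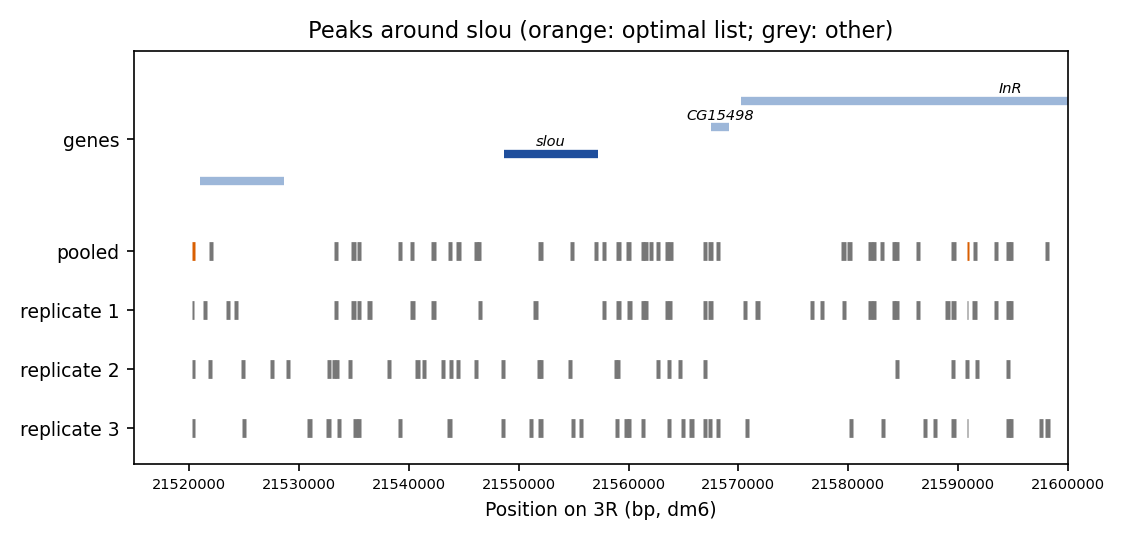
Peaks of the pooled list and of each replicate list along 3R (dm6, position in bp), with protein-coding genes drawn above as bars. Orange marks peaks of the optimal list and grey all others. The slou gene carries no orange peak, and the optimal summits nearest to its TSS and to its body lie 33679 bp and 28281 bp away.

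The replicates were compared to ask how far each carries the optimal peaks. On average 82.8% ± 3.04 (SD, n = 3) of the optimal peaks were matched among the top 2743 peaks of a replicate. The shares were 79.3% (95% interval 77.7 to 80.8) in replicate 1, 84.4% (83.0 to 85.7) in replicate 2 and 84.7% (83.3 to 86.0) in replicate 3. Random placement along the arms gave 1.53%, 1.46% and 1.51%, and at most 2.30% in any draw. The optimal peaks were the highest-scoring of the list called on these 3 replicates pooled. Overlap above random placement was therefore built in and is not independent evidence of reproducibility. In all 3 replicates 1664 peaks were matched (60.7%, 58.8 to 62.5), in exactly 2 replicates 754, in 1 replicate 314 and in none 11. Support in all 3 was 99.3% for ranks 1 to 686, 90.8% for ranks 687 to 1372, 43.2% for ranks 1373 to 2057 and 9.33% for ranks 2058 to 2743. Over whole replicate lists of 30000 peaks, support in all 3 was 98.3%, and 95.6% for ranks 2058 to 2743, against 4.34% in random placements.

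**Figure D2:**
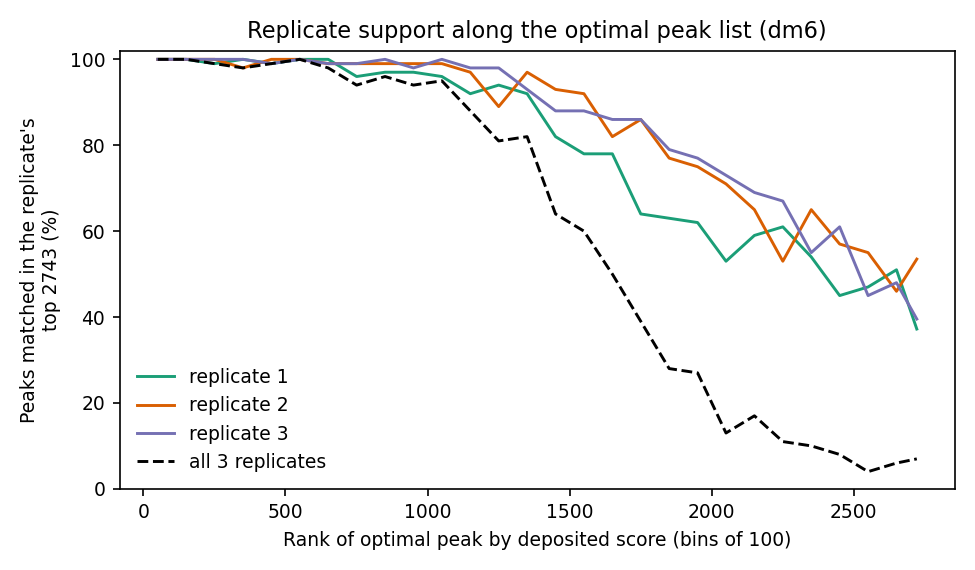
Share of optimal peaks (%, vertical axis) matched among the top 2743 peaks of each replicate, in bins of 100 peaks by rank of the authors' score (horizontal axis). Coloured lines are the replicates and the dashed line is a match in all 3, which was 99.3% over ranks 1 to 686 and 9.33% over ranks 2058 to 2743.

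Replicates 2 and 3 shared most, with 74.9% of the top peaks of replicate 2 overlapping those of replicate 3 and a rho of 0.722 across overlapping peaks. Replicates 1 and 3 shared 72.3% (rho 0.683), and replicates 1 and 2 shared 69.9% (rho 0.669). The mean was 72.4% ± 2.5 (SD over 3 pairs). No test of a difference between replicates was run, because each pair gives a single value.

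Optimal summits were concentrated just upstream of TSSs. Of the 2743 summits, 1538 (56.1%, 54.2 to 57.9) lay within 500 bp of a protein-coding TSS, against 19.7% (19.2 to 20.1) of background summits. The odds ratio was 5.21, with a p by Fisher's exact test too small for double-precision arithmetic, and 9.60 against uniform random positions. The median distance to the nearest TSS was 322 bp for optimal and 2732 bp for background summits. Of the optimal summits in the TSS class, 88.2% (86.5 to 89.7) were upstream, at a median of -113 bp, against 64.3% (63.0 to 65.6) of background summits. The TSS share was 66.3% (62.7 to 69.8) in ranks 1 to 686 and 47.4% (43.7 to 51.1) in ranks 2058 to 2743.

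Introns held 29.9% of optimal and 43.7% of background summits (odds ratio 0.548, exact p = 4.74e-46, adjusted p = 8.29e-46). Intergenic sequence held 11.3% against 23.7% (odds ratio 0.410, exact p = 1.35e-56, adjusted p = 4.74e-56). The classes are exclusive, so the larger TSS share lowers the shares of the others. Outside the TSS class, introns held 819 of 1205 optimal and 11740 of 21565 background summits, a larger share of the optimal ones. Intergenic sequence held 310 and 6365 of them, still a smaller share of the optimal ones. The shares outside the TSS class were not tested. The coding sequence class, which leaves out summits within 500 bp of a TSS or in UTRs, held only 3 optimal summits. It held 1405 background summits (odds ratio 0.0198, exact p = 8.49e-56, adjusted p = 1.98e-55). That odds ratio was 0.00698 against uniform random positions, 0.0397 with the higher-scoring peaks and 0.0297 at equal A/T share. The odds ratio was 0.141 for 3′ UTRs (exact p = 1.43e-32, adjusted p = 2.00e-32; 0.0731 with peaks matched in all 3 replicates and 0.0768 with those matched in replicates 1 and 2) and 0.460 for 5′ UTRs (p = 0.00747, adjusted p = 0.00872). The call for 5′ UTRs, which rests on 11 optimal summits, was lost when the optimal peaks were limited to those matched in both replicates other than replicate 1, 2 or 3, which kept 2003, 1896 and 1847 peaks (odds ratio 0.545 to 0.573, adjusted exact p = 0.0804 to 0.114). It was also lost with the higher-scoring peaks (odds ratio 0.586), with those matched in all 3 replicates (0.621), against uniform random positions (0.559) and at equal A/T share (0.598). Noncoding exons did not pass, with an odds ratio of 0.754 (exact p = 0.0868, adjusted p = 0.0868).

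**Figure D3:**
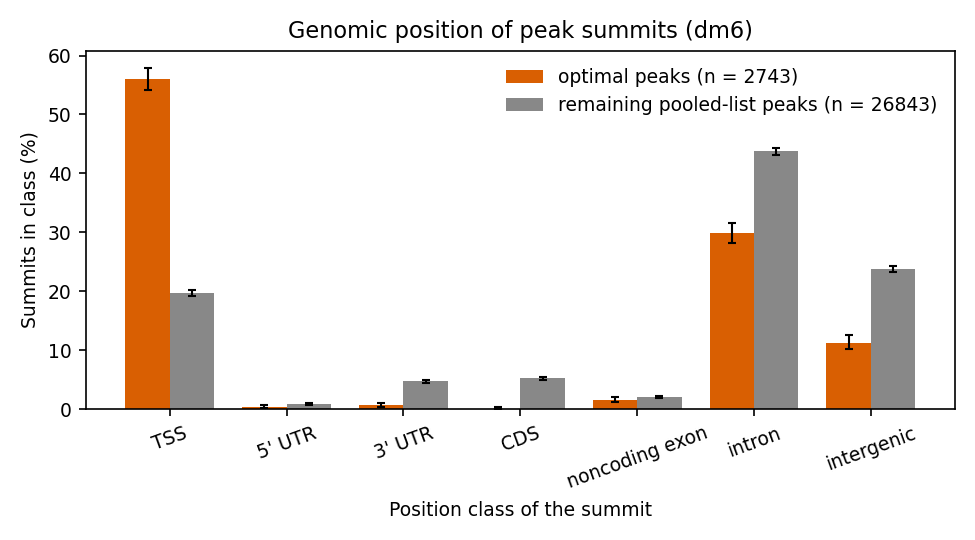
Share of peak summits (%, vertical axis) in each position class (horizontal axis) for the 2743 optimal peaks in orange and the 26843 background peaks in grey. Bars are shares and error bars are 95% Wilson intervals. The TSS class held 56.1% of optimal and 19.7% of background summits.

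Ribosomal protein genes were bound far more often than matched genes. Of 85 with a pooled-list peak, 64 were bound (75.3%, against 26.0% in random lists), and all 64 had a peak at their own TSS. The permutation p was 0.00020, the smallest that 10000 random lists can give, and the adjusted p was 0.00170. The highest peaks were at RpS27 (rank 78), RpL23A (rank 112), RpL7 (rank 119) and RpL32 (rank 144). Chemoreceptor genes of the Or, Gr and Ir families were bound less often, at 2 of 57 (3.51% against 29.3%, permutation p = 0.00020, adjusted p = 0.00170). These were Ir60b and Gr32a, and the peak at Gr32a lay at the TSS of another gene. Cuticle protein genes of the Cpr family were also bound less often, with Cpr73D the single bound gene of 26 (3.85% against 26.4%, permutation p = 0.00700, adjusted p = 0.0397). With all protein-coding genes in the random lists, the difference from them was -15.6 percentage points for chemoreceptor genes in place of -25.8, and -12.5 for Cpr genes in place of -22.6. The Cpr call was lost with the 1371 higher-scoring peaks (adjusted permutation p = 0.144) and with the peaks matched in all 3 replicates (adjusted p = 0.0873).

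None of the lists of muscle genes passed the test. Of 19 muscle identity factors with a pooled-list peak, 4 were bound (21.1%, against 38% in random lists, permutation p = 0.190, adjusted p = 0.539). These were org-1 (rank 577), Mef2, a general muscle differentiation factor (rank 1026), Poxm (rank 1084) and tin, the NK-type gene of heart and dorsal mesoderm (rank 1832). Among myoblast fusion genes 5 of 12 were bound, the highest at kirre, mbc, siz and Vrp1 (permutation p = 1, adjusted p = 1). Among sarcomere genes 4 of 18 were bound, namely Msp300 (rank 91), sls, Zasp52 and TpnC47D (permutation p = 0.331, adjusted p = 0.625). In replicates 1, 2 and 3 the highest optimal peak of Zasp52 ranked 11640, 1030 and 1125, and that of Vrp1 7477, 2791 and 1117. For mesoderm and muscle progenitor signalling 13 of 20 were bound, 65% against 40.3%, with a permutation p of 0.0440 that did not pass adjustment (adjusted p = 0.187), though it did without matching on length (adjusted p = 0.0187). The highest peaks of that list were at spi, which encodes an EGF receptor ligand and held 4 summits, and at numb, aos and ths.

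The lists for other tissues and factors did not pass either. Bound members were NK7.1 and tin of 10 NK-type homeobox genes (adjusted permutation p = 0.656) and hth, Antp and Ubx of 11 Hox and homeotic genes (adjusted p = 0.717). They were nkd and ptc of 12 segmentation genes (adjusted permutation p = 0.625), and zfh1, grh, OdsH and pros of 20 neural transcription factors (adjusted p = 0.401). With summits counted only within 1 kb of a TSS, the neural transcription factors were bound less often than random lists (adjusted permutation p = 0.0382). The neuronal genes elav and ChAT were bound of 11 (adjusted permutation p = 0.554), and the glial genes moody, nrv2, pnt and Gli of 7 (adjusted p = 0.656). In replicates 1, 2 and 3 the highest optimal peak of Ubx ranked 5933, 2323 and 1132, and that of Gli 5823, 2485 and 2077. Further lists gave ush and Hml of 7 haemocyte and fat body genes (adjusted permutation p = 1), fkh of 6 gut genes (adjusted p = 0.717), grh of 6 epidermis genes (adjusted p = 0.717), and bgcn and piwi of 9 germline genes (adjusted p = 0.825). Lists of this size limit what can be detected, since with 3 times the odds 54.5% of simulated lists of 19 genes and 26% of lists of 10 genes had a p under 0.05 before adjustment.

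**Figure D4:**
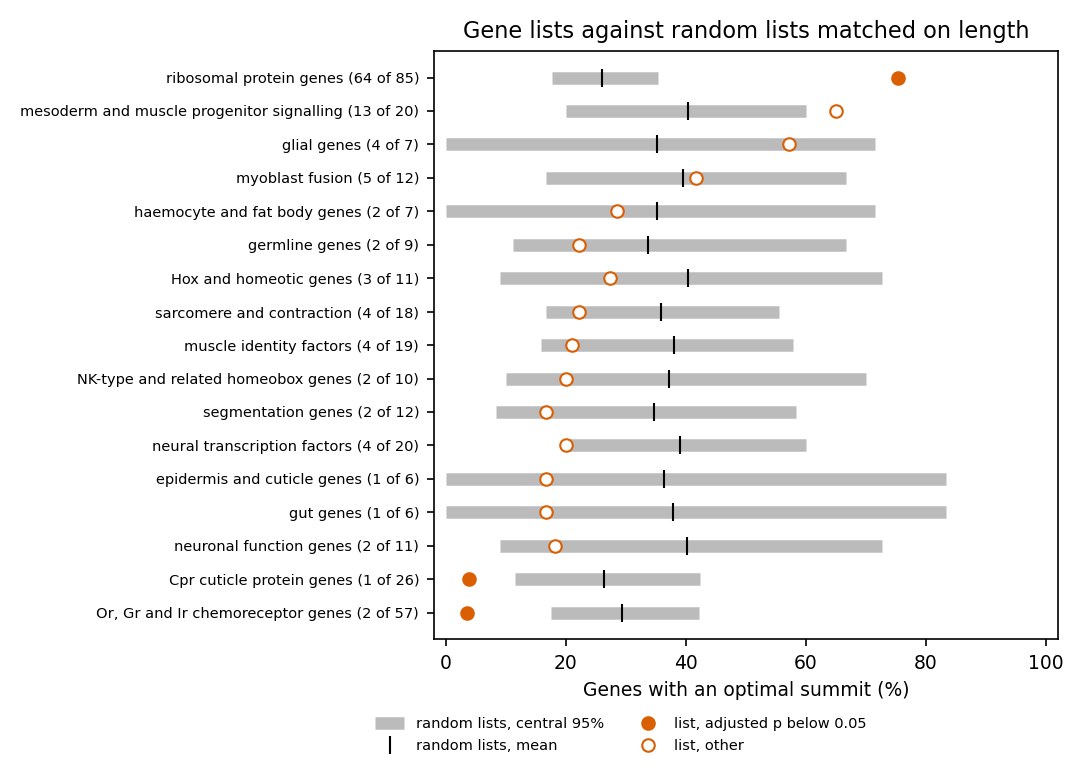
Share of each list's genes with an optimal summit (%, horizontal axis; circles), beside the mean (tick) and central 95% (grey bar) of 10000 random lists matched on length. Filled circles have an adjusted p below 0.05. Ribosomal protein genes stood at 75.3%, above their random lists, and chemoreceptor genes at 3.51%, below theirs.

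The homeodomain core TAATTA was more frequent at optimal summits than beside them. It was present within 50 bp of 297 summits (10.8%, 9.72 to 12), against 4.92% and 5.69% of the windows 500 bp to the left and right (exact McNemar p = 3.25e-16 and 1.28e-11). Background summits had it in 7.83% (odds ratio 1.43, exact p = 1.43e-07). TAATTG was present at 11.3% of optimal summits, against 9.15% and 8.24% beside them (exact McNemar p = 0.00839 and 0.000108), and 10.7% of background summits (odds ratio 1.07, p = 0.285). Optimal summits were also richer in A and T, at 66.7% ± 8.68 (SD over 2743 windows), against 55.8% beside them and 60.5% at background summits. At equal A/T share, a comparison chosen after seeing the data, the odds ratio of TAATTA at optimal summits was 0.926 against background peaks (95% interval 0.811 to 1.06) and 0.966 against side windows (0.801 to 1.17). For TAATTG these were 0.884 (0.778 to 1) and 0.809 (0.682 to 0.961).

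Of all strand-merged 6-mers, 484 were more and 959 less frequent at summits than beside them at an adjusted p below 0.05. All 36 made of A and T alone were more frequent, and they were 29 of the 30 with the smallest p. The leading 6 were TTAAAA (35.0% of summits against 12.5% of side windows, odds ratio 3.76, exact p = 4.25e-121, adjusted p = 8.84e-118), AAATAT, ATTTTA, ATTTAA, TAAATA and AAAATA. CTCCTC was less frequent (0.875% against 5.89%, odds ratio 0.141, exact p = 5.67e-33, adjusted p = 3.57e-31), as was GGAGGA (1.02% against 5.61%). Against background peaks in place of side windows, 340 6-mers were more and 774 less frequent. At equal A/T share, chosen after seeing the data, 157 were more and 87 less frequent against side windows, and 106 more and 45 less frequent against background peaks. Of the 36 made of A and T, 9 were then more frequent than in side windows and 27 did not pass. Against background peaks 6 were more frequent, 29 did not pass, and AAAAAA, named after its value was seen, was less frequent (odds ratio 0.817, 0.744 to 0.898). TTAAAA had an odds ratio of 1.48 (1.30 to 1.68) against side windows and 1.19 (1.09 to 1.31) against background peaks of equal A/T share. AAAATA passed against neither, and GGAGGA only against side windows (odds ratio 0.425, against 0.569 for background peaks). The odds ratio of CTCCTC was 0.357 against side windows and 0.462 against background peaks of equal A/T share, and 0.264 against background peaks of any A/T share.

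**Figure D5:**
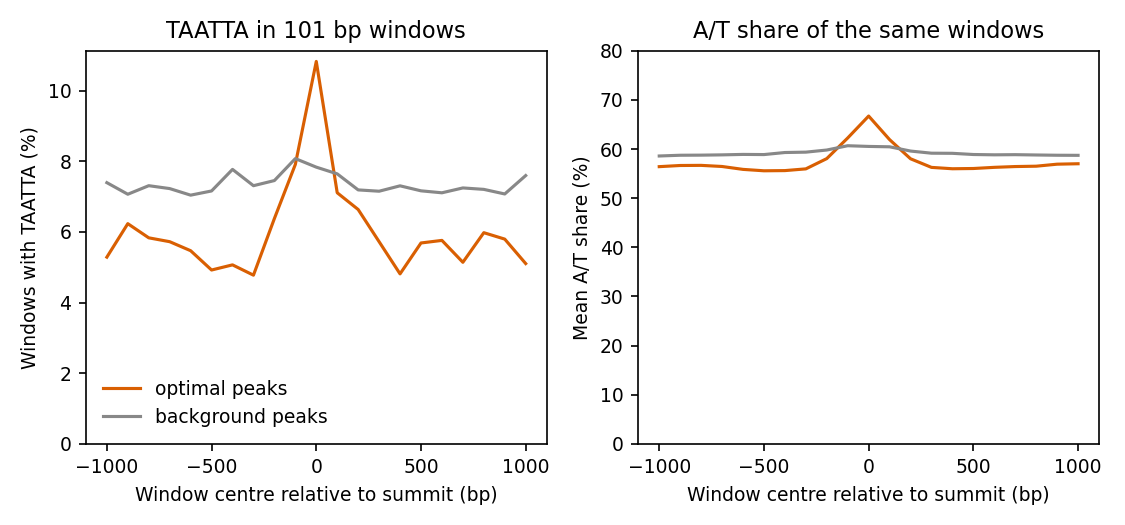
Share of windows with TAATTA (%, left) and mean A/T share (%, right) by distance of the window centre from the summit (bp, horizontal axes), for optimal peaks in orange and background peaks in grey. Both rise at optimal summits, to 10.8% and 66.7%.

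The X chromosome held 18.2% of optimal and 14.3% of background peaks (odds ratio 1.33, exact p = 1.57e-07, adjusted p = 4.72e-07). Chromosome 4 held 12 optimal peaks (odds ratio 0.242, exact p = 1.46e-09, adjusted p = 8.79e-09) and 2L 21.2% against 25% (odds ratio 0.808, p = 9.81e-06, adjusted p = 1.96e-05). Arms 2R, 3L and 3R did not pass, with odds ratios of 1.01, 0.974 and 1.1 (exact p = 0.862, 0.626 and 0.0527, adjusted p = 0.862, 0.751 and 0.0791). The X and 2L values depended on the reference. Background peaks numbered 285 per Mb on 2L, 216 on 2R, 180 on 3L, 164 on 3R and 163 on X. Optimal peaks numbered 24.8, 22.3, 18.0, 18.1 and 21.2 per Mb on the same arms. Against arm length, by an exact binomial test, the X odds ratio was 1.07 (adjusted p = 0.149), that of 2L 1.31 (adjusted p = 1.60e-07) and that of chromosome 4 0.444. Against protein-coding TSSs, a reference chosen after seeing the data and adjusted over 7 arms with Y, 2L (odds ratio 1.16) and 3R (0.868) passed, each at an adjusted exact p of 0.0157. X (1.09) and chromosome 4 (0.603) did not, each at an adjusted exact p of 0.151. When the optimal peaks were also limited to the 1538 in the TSS class, no arm passed and 2 had an unadjusted exact p below 0.05, with odds ratios of 0.850 on X, 1.18 on 2L and 0.627 on chromosome 4.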

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

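Comparisons at equal A/T share, comparisons with protein-coding TSSs and single replicate pairs were chosen after seeing the data, and the other alternatives before. The TSS odds ratio and the ribosomal and chemoreceptor lists kept their direction and their side of the threshold in all alternatives run, with a TSS odds ratio of 9.60 against uniform random positions, as did TAATTA against the side windows in all but equal A/T share. Mean replicate support was 76.3% with 50% reciprocal overlap, 78.8% with summits within 100 bp, 50.7% with lists of 1371 and 95.9% with lists of 5486. Support in all 3 replicates was 51.6%, 53.6%, 33.4% and 88.0% under the same settings, and 67.3% to 73.0% in both remaining replicates when each was left out. Pair agreement was 67.9%, 64.4%, 75.6% and 62.6%, and 69.9% to 74.9% in single pairs. Shorter lists can match fewer peaks and longer lists more by construction. The optimal list fell to 1371 peaks in the higher-scoring part and to 1664 matched in all 3 replicates, because each keeps fewer peaks.

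Against arm length 5 arms passed in place of 3, with odds ratios turned to 1.31 on 2L and 0.885 on 3R, and 1.07 on X no longer past the threshold. With all optimal peaks against protein-coding TSSs 2 arms passed, 2L at 1.16 and 3R at 0.868, with X at 1.09 and chromosome 4 at 0.603 no longer past the threshold and 2R at 0.997. With the peaks also limited to the TSS class 0 arms passed by Fisher's exact test and 2 had an unadjusted p below 0.05, with X at 0.850, 2L at 1.18, 3R at 0.957 and chromosome 4 at 0.627. Both were adjusted over 7 arms with Y. The cause was not tested for arms other than X. The Cpr difference from random lists, in percentage points, was -15.4 with the higher-scoring peaks and -17.2 with those matched in all 3 replicates, no longer past the threshold. The cause was not tested. Lists that were not past the threshold in the report also turned direction. Myoblast fusion went to -14.6 and -1.54 in those settings and -5.89 to -3.59 when each replicate was left out, and germline genes to 2.37 and 0.0144. Haemocyte and fat body genes ranged from -11.4 to 1.44 when each replicate was left out, the last without replicate 1. Others kept their direction but shrank. Without replicate 3, muscle identity factors went from -16.9 to -6.13 and NK-type genes from -17.2 to -6.33. Without replicate 1, Hox and homeotic genes went from -13.1 to -4.65. With summits within 1 kb of a TSS, haemocyte and fat body genes went to 8.51, NK-type genes to 8.37 and progenitor signalling to -3.10. At equal A/T share the background odds ratio turned to 0.926 for TAATTA and 0.884 for TAATTG, and the latter was 0.991 within 100 bp of the summit. Against side windows of equal A/T share the odds ratio turned to 0.966 for TAATTA and 0.809 for TAATTG. More and less frequent 6-mers numbered 340 and 774 against background peaks of any A/T share, 157 and 87 against side windows of equal A/T share, and 106 and 45 against background peaks of equal A/T share. Among values that do not answer a main comparison, some of them given above, 230 kept their call or value. Of the others, 10 lost the call, 4 gained it, 15 turned direction and 5 moved. The 5 were rank correlations, at 0.722 to 0.726 in place of 0.692, and numbers of bound genes, at 1607 and 1820 in place of 2748. Depth is unknown, so its effect could not be assessed.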

Other observations

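The tests of promoters on both strands, symbol families, tRNA genes, 6-mers at equal A/T share, and TAATTA against side windows of equal A/T share or outside the TSS class were chosen after the main results were seen. Promoters with TSSs on both strands made up 651 of the 1538 optimal summits in the TSS class (42.3%, 39.9 to 44.8), against 17.4% (16.4 to 18.5) of background summits in that class (odds ratio 3.47, Fisher's exact p = 2.85e-84). A summit between TSSs that point away from each other is upstream of both, so this share and the upstream share are not independent. Among families picked by symbol, mitochondrial ribosomal protein genes were bound at 26 of 58 (44.8%, against 22.1% in random lists, permutation p = 0.00040, adjusted p = 0.00480 over 12 families), with the highest peaks at mRpL41 (rank 3) and mRpS10 (rank 9). The peak at rank 9 is the one given above for Art3, whose TSS is the nearest at 117 bp. Cytochrome P450 genes were bound at 3 of 37 (8.11% against 30.7%, permutation p = 0.00100, adjusted p = 0.00600). Of 8 families picked to stand for genes that every cell uses, 7 had a share above the mean of their random lists, 6 of them without passing the permutation test. Of 3 families picked for restricted use with more than 1 gene tested, 3 were below that mean, 2 of them without passing. Where the single members of these families are expressed was not checked. Only 5 optimal summits lay within 200 bp of a tRNA gene (0.182%, against 0.224% of background summits, odds ratio 0.815, exact p = 0.831).

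The 6-mers named here were chosen after their values were seen. Their odds ratios are within classes of equal A/T share while their shares are of all summits. They were not compared within position classes. The TSS class held 56.1% of optimal and 19.7% of background summits. A sequence common at promoters could therefore differ for that reason alone. CGATAG was present at 6.85% of optimal and 3.20% of background summits (odds ratio 2.72, 95% interval 2.31 to 3.21), CGCTAG at 2.52% against 1.43% (2.52, 1.93 to 3.28) and GCGCCA at 4.56% against 3.84% (2.21, 1.81 to 2.70). TATCGA was at 9.11% against 4.99% (odds ratio 1.93, 1.68 to 2.23) and ATCGAT at 6.64% against 3.98% (1.86, 1.58 to 2.19). The last pair are parts of the DNA replication-related element of promoters, the site of the factor Dref. ACACTG, which lies within a promoter element bound by M1BP, was at 7.95% against 5.49% (odds ratio 1.67, 1.44 to 1.95).

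The position of optimal summits at TSSs was set against base composition, and within classes of equal A/T share the TSS odds ratio was 5.10 (4.69 to 5.54), which argues against A/T-rich DNA alone driving the peak calls. A preference for genes that every cell uses was a hypothesis raised by the ribosomal protein genes, with mRpL41 already seen among the highest peaks. Of 8 further families picked by symbol to stand for such genes, 1 passed. A count of 0 or 1 had been set beforehand as the result against such a preference. Simulated draws of the 8 families, added after the count was seen, gave 0 or 1 in 4% of 200 draws with 3 times the odds. With 2 times the odds, a size given weight only after both shares were seen, 64.5% of draws gave 0 or 1, so a preference of that size stays open. The count takes each family singly, and the families were not tested together. Of the 8, 7 had a share above the mean of their random lists. Recovery of open promoter chromatin without the tagged protein may also place peaks there and stays open, since no control library was analysed here.

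The excess of TAATTA at summits may follow from base composition. At equal A/T share the odds ratio was 0.926 (0.811 to 1.06) against background peaks and 0.966 (0.801 to 1.17) against side windows, the values foreseen if A/T share accounts for the excess. At any A/T share the odds ratio against background peaks was also 1.39 (1.15 to 1.68) outside the TSS class, so the excess was not limited to that class. The criterion for this value was written after the data were seen, so it is not used against a promoter signal. At equal A/T share the odds ratio was 0.949 (0.776 to 1.16) in the TSS class and 0.911 (0.750 to 1.11) outside it. Since it fell in both, the value in the TSS class leaves a promoter signal open there. The intervals leave room for a small excess, and the design, with 1 group, gives no biological explanation to test.

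Low-ranked peaks were dense around slou, and the list of peaks there had been seen before the comparison with other genes was made. Of 45 other homeobox and muscle identity genes, 0% had as many as the 25 pooled-list peaks of slou within 20 kb, where their median was 11 and their highest count 20. This is what extra copies of the slou region from the transgene might give, as a hypothesis. In single replicates 4, 2 and 0 of the 45 genes had as many peaks as slou in replicates 1, 2 and 3. Of 2000 random protein-coding genes, 0.95% had as many peaks as slou in the pooled list. In replicates 1, 2 and 3 these shares were 12.05%, 1.1% and 3.3%. True binding near slou stays open, and the extent of the inserted DNA is not given in the sources used here.

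For the X chromosome, the odds ratio of optimal peaks in the TSS class was 0.850 (0.734 to 0.983) with protein-coding TSSs as the reference. That of all optimal peaks was 1.09 with the same reference. Within position classes, that of all optimal against background peaks was 1.26 (1.13 to 1.4). The last value argues against a different mix of position classes on X as the source of the excess there. A low number of background peaks on X stays open, though its 163 per Mb were near the 164 of 3R.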
